A study of Drosophila melanogaster with 18 samples.

How the data were processed

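RNA of Drosophila Schneider 2 (S2) cells was measured on 18 spotted DNA arrays with 2 channels each. The arrays fall into 6 groups of 3: cells without RNAi (control), cells treated with double-stranded RNA against XBP-1, and cells treated with double-stranded RNA against IRE1, each without DTT and after 7.4 hours in 2 mM DTT. Per the labels' protocols, double-stranded RNA was added at about 15 µg/ml in 3 rounds over about a week, 16 µg of total RNA was labelled with Cy5, and every array carried the same Cy3-labelled reference, a pool of S2 cells with and without DTT and of embryos. The labels give each array a replicate letter (A, B or C) and call the experiments triplicate. They do not say that the letters mark separate cultures, so the p-values measure the spread between these samples, which may be technical. Groups and letters were taken from the sample titles. Control cells received no double-stranded RNA, so differences between RNAi and control include any effect of double-stranded RNA as such.

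The deposited values are log ratios, read here as sample over reference and as log2. Per the labels, the authors normalized the arrays in the NOMAD database and removed spots under 1.5-fold above background, spots with an R2 of the 2 channels under 0.5 and visibly defective spots. The array scanner's intensities were not used here. The table does not state the base of the logarithm or the direction of the ratio. The range of the values is too wide for base 10, and the natural logarithm was not excluded, so every log2 size below rests on that reading. The labels give Cy5 for the sample and Cy3 for the reference but not the numerator, so the direction was assumed to be Cy5 over Cy3, sample over reference. It was checked with tissue markers that the embryos in the reference could supply and S2 cells should lack. Of the 12 measured, 11 lay below the median of all probes, with a median log2 ratio of -0.91 against -0.26, and the muscle myosin gene Mhc stood at -2.57. No scaling between arrays is stated, and array medians ran from -0.81 to 0.24.

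The table holds 7257 probes, of which 2737 have a value on all 18 arrays, and 18.8% of its cells are empty. An array held between 3755 values (replicate A of the arrays labelled IRE1 RNAi with DTT, 48.3% empty) and 6696 values. Signal and background per spot were not analysed here, so the number of arrays and the removed spots limit the precision. Arrays of the same group correlated with r between 0.639 and 0.876 across probes, and at most 1.27% of their values were identical, so no array was counted as a duplicate.

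Probe names were first taken from the platform annotation, and the gene list results under that naming were seen before it was given up. No list passed the threshold under it, known genes of the endoplasmic reticulum (ER) stress response included, so the change of naming followed a look at the outcome. The probe numbers were then read as CG gene numbers and matched to the locus tags and synonyms of the Release 6 annotation; matching lists by CG number first had been fixed before the data were examined. The evidence for CG numbers was as follows. The share of probe numbers that are CG numbers uses no array values, so it is free of the response to DTT. The correlations were taken across arrays with and without DTT. They can therefore include that response and are not evidence independent of it. Of the probe numbers, 99.9% are CG numbers, against 69.7% of all whole numbers in the same range. The 56 complete probes of ribosomal proteins under CG naming had a median pairwise correlation across arrays of 0.699, against -0.563 for the 6 under the platform's naming. Pairs of probes of the same gene correlated with a median of 0.686 over 32 pairs, against 0.037 over 80 pairs under the platform's naming and -0.012 for 5000 random pairs. The platform's symbol equalled the CG gene for 1 of 4750 probes. By CG number 6683 probes matched a locus tag and 457 a synonym, 107 matched several genes and 10 none, and the last 2 sets were left unnamed. In all 6980 genes were named, 153 of them with several probes.

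Each probe was fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes) in a model of 6 group means on 18 arrays, on the log2 ratios as deposited, with at least 2 values in each group of a contrast. The 8 contrasts were the effect of DTT in control, XBP-1 RNAi and IRE1 RNAi cells, the 3 pairwise differences of these effects, and the effect of each RNAi without DTT. Adjusted p-values are Benjamini-Hochberg values from limma within a contrast, 2-sided, with a threshold of 0.05. Errors after ± are standard errors from limma, with 3 arrays per group unless a spot was removed. Of the 14 gene lists, each was tested in the 8 contrasts with limma's cameraPR at a preset inter-gene correlation of 0.01, adjusted over all 112 tests. Of the 54 list tests past the threshold, 2 remained so with the correlation estimated from the residuals (0.253 to 0.779 by list): the ER chaperone list in XBP-1 RNAi minus control and in IRE1 RNAi minus XBP-1 RNAi. That correlation was estimated on the arrays as deposited, so shifts of whole arrays enter it and may make these p-values too large. With fit and correlation both taken after centring and replicate block, chosen after seeing the data, 27 of the 54 remained. A list used 1 probe per gene, that with most values. Asparagine synthetase was left out of its list, since the CG number written for it belongs to another gene.

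Classes of genes that fell or rose with DTT were chosen on the 6 control arrays alone and compared on the 12 RNAi arrays by an exact permutation test of 400 arrangements of the RNAi labels, whose smallest 2-sided p is 0.005. Counts of genes in 2 intersection classes were taken from the fits. The genes named are IRE1, XBP-1, Hsc70-3 and SPARC, and then those given by a rule. Among probes past the threshold with a value on every array of the contrast, exactly 1 gene name and groups that did not overlap, these were the 10 that rose and 10 that fell most in control cells, and 5 and 5 in other contrasts. To these came the 10 with the largest difference per intersection class, and per list up to 4 members past the threshold, or up to 2 below it in lists with none past it. For differences of effects, groups that do not overlap was read as the 9 pairwise differences of an arm lying apart from those of the other arm, a reading settled after a first run and naming the same genes. Groups, contrasts, lists, the naming rule and most alternatives were fixed before the data were examined.

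Same-lettered arrays deviated together. In 7 contrasts every pair's correlation of deviations from the group means was over 0.1, with a lowest value of 0.231. In XBP-1 RNAi minus control 17 of 18 pairs were, with a lowest of 0.012, so there the letters were not taken to pair the arrays. With the letter as a block and the arrays as deposited, limma estimated an infinite prior degree of freedom in all 8 contrasts, which gives every probe the same residual variance. Array-wide shifts left in the residuals could give this, so the p-values of the block alone are probably too small and its counts are given as a limit, not as a stronger result. The prior degrees of freedom were 17.3 to 18.3 as deposited, 5.17 to 5.23 with centring and 7.49 to 8.11 with centring and block. They were also infinite in 3 of the 8 fits on the arrays of the contrast alone. Among these was DTT in control cells, the fit that chose the classes as deposited, so that choice used 1 common variance for all probes. Alternatives were median centring, quantile normalization, the replicate letter as a block, complete probes, probes with at least 1 value per group, the arrays of the contrast alone, array weights, a fold minimum of 1.5, classes chosen by 1.5-fold with no test, and leaving out each array. Centring together with the block, a correlation estimated in that fit, and the platform's naming were added after seeing the data.

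The fits were tested on simulated data with the residuals' spread of 5312 probes, 200 of them changed. The noise was drawn independently for each probe and array around each array's shift. It held no correlation between genes and no effect of the replicate letter on single probes, so the shares below may not hold for the real data. For the effect of DTT in control cells, 13.4% of changes of 1, 94% of changes of 2 and 100% of changes of 3 on the log2 scale were recovered, with 4.2% false calls. For IRE1 RNAi minus XBP-1 RNAi, 0% of changes of 1, 40.3% of changes of 2 and 95.5% of changes of 3 were recovered, with 1.1% false calls. With centring and block these shares became 61.2%, 95.5% and 100% for control cells and 17.9%, 80.6% and 95.5% for IRE1 RNAi minus XBP-1 RNAi. Tables and plots were made with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.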

Results

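The unfolded protein response was induced in S2 cells with the reducing agent DTT, which disrupts disulphide bonds of proteins folding in the ER. IRE1 is an ER membrane kinase and nuclease that splices the mRNA of the transcription factor XBP-1. The questions addressed were which mRNAs changed with DTT, and how the changes differed when XBP-1 or IRE1 was the target of RNAi.

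The mRNAs of both RNAi targets were examined first. The IRE1 probe was not lower on the arrays labelled IRE1 RNAi. Its log2 ratios there were 2.06, 2.06 and 0.13 without DTT (replicates A, B and C) and 0.80, 2.55 and 2.20 with DTT, while the other 12 arrays ran from -1.08 to 0.41. Group means without DTT were 1.42 ± 1.11 (SD, n = 3) for the arrays labelled IRE1 RNAi, -0.69 ± 0.09 for control and -0.53 ± 0.50 for XBP-1 RNAi. In limma the difference of the IRE1 probe between the arrays labelled IRE1 RNAi and control without DTT was 2.11 ± 0.47, with an adjusted p of 0.577 (0.996 with centring, 0.625 with centring and block). Adjusted over 5914 probes, 0.577 was the smallest adjusted p of that contrast in limma, so it does not show that the IRE1 probe was unchanged. The block alone gave the IRE1 probe an adjusted p of 4.23e-07 there, from 1 common variance of all probes. Without replicate C of the arrays labelled IRE1 RNAi without DTT the Ire1 probe's difference was 2.75 and passed. The group name is therefore kept as a label only, and every direction given for IRE1 RNAi is that of the arrays so labelled. The 2 XBP-1 probes differed between XBP-1 RNAi and control without DTT by -0.38 ± 0.36 and -0.41 ± 0.36, both with an adjusted p of 0.959 (0.742 with the block, 0.276 with centring and block). The Xbp1 probes thus did not pass the test adjusted over all probes, although they were lower than control of the same letter in 6 of 6 pairs without DTT and 4 of 6 with DTT. After centring they were lower in all 12 pairs. These pairs count 2 probes on the same arrays. With DTT in control cells the XBP-1 probes changed by 0.26 (adjusted p = 0.755) and 0.31 (adjusted p = 0.689).

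**Figure D1:**
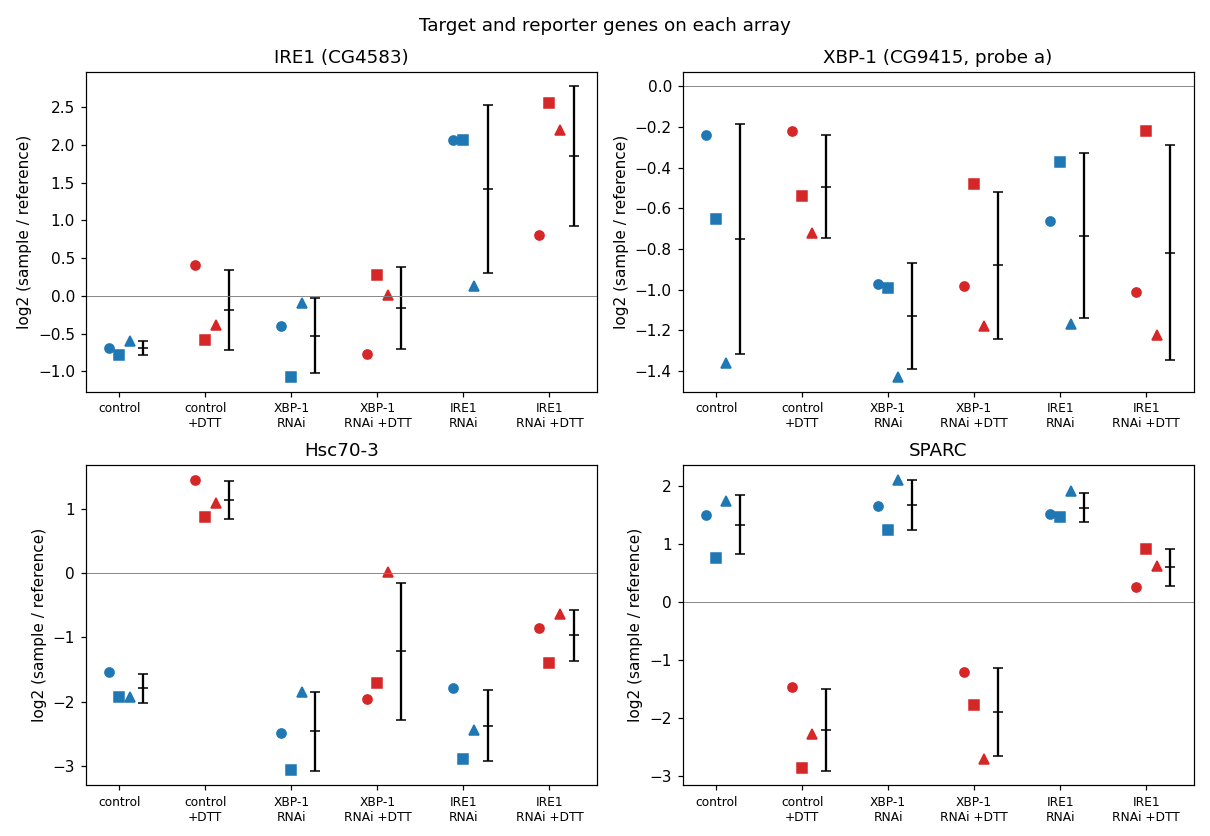
Log2 ratio of sample over reference (vertical axis) on each of the 18 arrays for IRE1, an XBP-1 probe, Hsc70-3 and SPARC, by group, without DTT in blue and with DTT in red. Points are arrays with a shape per replicate letter, and bars are the mean ± SD of 3 arrays; the IRE1 probe reached 2.55 on an array labelled IRE1 RNAi.

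Among the genes named by the rule, DTT raised lactate dehydrogenase most in control cells, followed by genes that include a cytochrome P450 and glutathione transferases. Ldh rose by 5.86 ± 0.41 on the log2 scale (58.1-fold). Cyp6a20 rose by 4.27 ± 0.45, GstE8 by 4.04 ± 0.36, CG3348 by 4.01 ± 0.43 and GstE9 by 3.98 ± 0.45. Next were CG6330 by 3.86 ± 0.38, Picot by 3.83 ± 0.41, GstE11 by 3.76 ± 0.39, CenG1A by 3.70 ± 0.39 and GstE7 by 3.61 ± 0.41. Hsc70-3, the ER chaperone BiP, rose by 2.92 ± 0.43 (adjusted p = 1.36e-05). Several genes of matrix and other secreted proteins were among those that fell most. The matrix glycoprotein SPARC changed by -3.54 ± 0.40, Idgf6 by -3.47 ± 0.53, Idgf2 by -3.44 ± 0.45 and Idgf3 by -3.43 ± 0.39. The collagen gene vkg changed by -3.13 ± 0.39 and the laminin gene LanB2 by -3.07 ± 0.36. The protease CtsL1 changed by -3.40 ± 0.41, Nepl19 by -3.23 ± 0.34, the mitotic phosphatase stg by -3.32 ± 0.37 and the cytosolic chaperone Hsp83 by -3.11 ± 0.35.

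In limma 430 of 5935 probes rose and 264 fell with DTT in control cells, while the median change of all probes was 0.15. The share of calls that were higher was 62% as deposited, 48.1% after each array was centred on its median and 48.9% with quantile normalization. Both scalings by themselves pull this share towards equal parts, so it is given without a cause, here and below. With the replicate letter as a block 1164 probes passed the threshold. In that fit, here and below, limma gave every probe 1 common variance, so its p-values are probably too small. The count ran from 467 without replicate C of control with DTT to 738.

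Lists fixed in advance gave the following in control cells, with medians relative to all probes. Of 26 cell cycle and DNA replication genes 17 fell, and 20 adjusted over the list alone (median -1.58, adjusted p = 2.89e-16; adjusted p = 0.213 with an estimated correlation), stg, Mcm7 (-2.04) and Cdk1 (-2.04) among them. Of 37 secreted and matrix genes 14 fell, and 17 adjusted over the list alone (median -1.13, adjusted p = 3.1e-12; adjusted p = 0.213 with an estimated correlation). Of 23 glutathione and thiol genes 13 rose and 1 fell, and 16 and 2 adjusted over the list alone (median 1.68, adjusted p = 6.49e-11; adjusted p = 0.236 with an estimated correlation), GstE6 (3.41) and GstD9 (3.38) among them. Of 21 genes of the PERK-ATF4 arm and tRNA synthetases 9 rose, and 14 adjusted over the list alone (median 1.00, adjusted p = 7.96e-07; adjusted p = 0.374 with an estimated correlation), led by the translation inhibitor Thor (2.73) and the synthetases AspRS (2.54), ValRS (2.16) and TrpRS (2.03).

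Of 13 ER chaperones and folding enzymes 7 rose in control cells, and 8 adjusted over the list alone (median 1.02, adjusted p = 5.42e-06; adjusted p = 0.349 with an estimated correlation). Ero1L, an ER oxidase, rose by 3.50, Sil1 by 3.43 and P58IPK by 1.86. Of 25 ER-Golgi transport genes 9 rose, and 11 adjusted over the list alone (median 0.65, adjusted p = 0.000706; adjusted p = 0.555 with an estimated correlation), Sec22 (2.37), Syx5 (2.14), betaCOP (1.56) and Grasp65 (1.49) among them. Of 60 ribosomal protein genes 1 rose, and 0 adjusted over the list alone (median 0.34, adjusted p = 0.0341; adjusted p = 0.928 with an estimated correlation), which centring took to 0.0663 and quantile normalization to 0.0734. None of 40 proteasome genes passed, with 0 adjusted over the list alone (median -0.41, adjusted p = 0.019; adjusted p = 0.882 with an estimated correlation).

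The other 6 lists did not pass in control cells. They were ER-associated degradation (3 of 11 rose, Herp by 2.15, Hrd3 by 1.48 and Der-2 by 1.31, and 4 adjusted over the list alone, adjusted p = 0.0579), translocation (2 of 20 rose and 1 fell, and as many adjusted over the list alone, adjusted p = 0.974), and N-glycosylation (0 of 18, and 0 adjusted over the list alone, adjusted p = 0.159). Lipid and sterol synthesis had 4 of 14 up and 1 down, 4 and 2 adjusted over the list alone (adjusted p = 0.96), with AcCoAS at -2.06 and SREBP at 1.52. The tissue markers foreign to S2 cells had 1 of 12 down, Act57B at -1.90, and 1 adjusted over the list alone (adjusted p = 0.566). Cytosolic heat shock genes went both ways, 2 of 11 up and 3 down, and 4 and 3 adjusted over the list alone (adjusted p = 0.91), with Hsp26 at 3.53, Hsp27 at 1.48, Stip1 at -1.75 and DnaJ-1 at -1.20. Single control arrays ended some of these calls. Hrd3 was no longer past the threshold without replicate C of control with DTT (1.28). Der-2 was not without B of control without DTT (1.16), or without A (1.10) or C (1.16) of control with DTT. Hsp27 was not without B of control without DTT (1.10) or C of control with DTT (1.36). Other list members whose calls ended without at least 1 control array were Sec61alpha, Srp68, Pis, ATPCL and RpS19a.

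**Figure D2:**
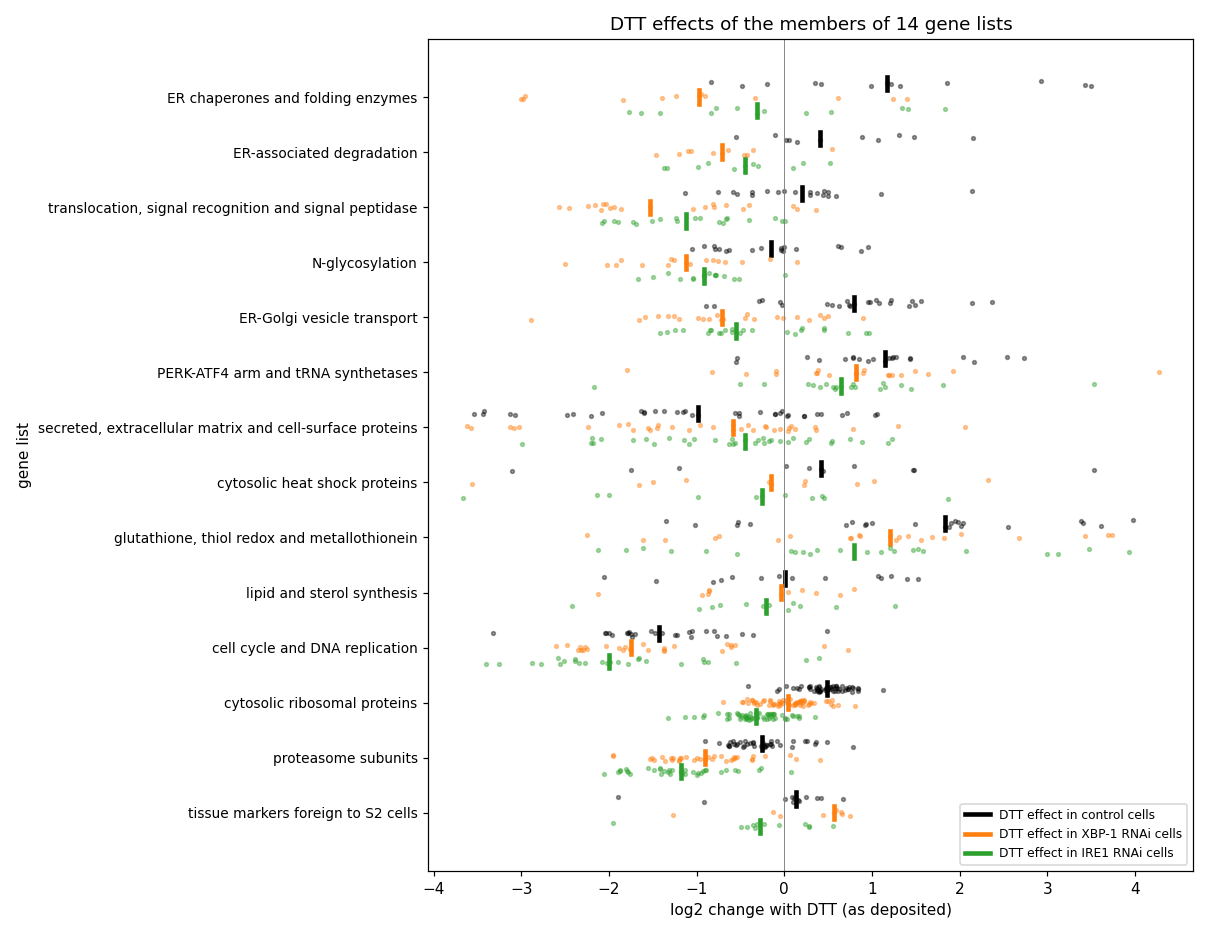
Log2 change with DTT (horizontal axis), as deposited, of the members of 14 gene lists (vertical axis) in control (black), XBP-1 RNAi (orange) and cells of the arrays labelled IRE1 RNAi (green). Dots are genes and vertical bars are medians; in control cells the cell cycle list lay at -1.58 and the ER chaperones at 1.02 relative to the median of all probes.

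Under XBP-1 RNAi, the translation inhibitor gene Thor and the glutathione transferase gene GstE8 were among those that rose most with DTT, and SPARC and Hsp83 among those that fell most. CG3348 rose by 5.48 ± 0.42, Dgp-1 by 4.67 ± 0.41, Thor by 4.27 ± 0.42, Ptp52F by 3.87 ± 0.35 and GstE8 by 3.85 ± 0.36. Agpat2, a lipid acyltransferase, changed by -4.08 ± 0.51, Idgf6 by -3.88 ± 0.52, Idgf2 by -3.62 ± 0.45, SPARC by -3.57 ± 0.40 and Hsp83 by -3.56 ± 0.35. Hsc70-3 rose by 1.24 ± 0.42 (adjusted p = 0.0414), a call that quantile normalization ended (adjusted p = 0.214).

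In limma 256 of 5649 probes rose and 665 fell with DTT under XBP-1 RNAi, with a median change of all probes of -0.08. Higher calls were 27.8% as deposited, 43.9% with quantile normalization and 54.8% with centring, so falls outnumbered rises in the first 2 of these and not in the last. The block gave 1504 probes, and without replicate C of XBP-1 RNAi with DTT 526 probes passed. Hsc70-3 was also no longer past the threshold without that array (0.63), or without replicate A (1.23) or B (0.95) of XBP-1 RNAi without DTT.

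Of 27 cell cycle genes 19 fell under XBP-1 RNAi, and 20 adjusted over the list alone (median -1.67, adjusted p = 1.05e-11; adjusted p = 0.349 with an estimated correlation), Mcm3 at -2.60. Of 21 translocation genes 11 fell, and 15 adjusted over the list alone (median -1.45, adjusted p = 7.47e-08; adjusted p = 0.349 with an estimated correlation), Tapdelta at -2.46. Of 17 N-glycosylation genes 9 fell, and 11 adjusted over the list alone (median -1.04, adjusted p = 2.55e-06; adjusted p = 0.349 with an estimated correlation), OstDelta at -2.50 and Stt3B at -2.03. Of 37 proteasome genes 16 fell, and 17 adjusted over the list alone (median -0.82, adjusted p = 4.91e-06; adjusted p = 0.555 with an estimated correlation), Prosalpha4 at -1.95. Of 13 ER chaperones 2 rose and 6 fell, and 2 and 9 adjusted over the list alone (median -0.90, adjusted p = 0.000331; adjusted p = 0.49 with an estimated correlation), ERp60 at -2.98, Pdi at -2.96 and Calr at -1.84. Of 24 ER-Golgi genes 6 fell, and 7 adjusted over the list alone (median -0.63, adjusted p = 0.0332; adjusted p = 0.804 with an estimated correlation), CHOp24 at -2.89.

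Of 35 secreted genes 1 rose and 13 fell under XBP-1 RNAi, and 1 and 15 adjusted over the list alone (median -0.50, adjusted p = 1.74e-05; adjusted p = 0.477 with an estimated correlation). Of 23 glutathione genes 12 rose and 3 fell, and as many adjusted over the list alone (median 1.29, adjusted p = 1.43e-07; adjusted p = 0.349 with an estimated correlation). Of 21 PERK-ATF4 and synthetase genes 7 rose and 1 fell, and 8 and 1 adjusted over the list alone (median 0.90, adjusted p = 2.48e-05; adjusted p = 0.482 with an estimated correlation). The lists that did not pass were ER-associated degradation (4 of 11 fell, adjusted p = 0.0753), heat shock (1 of 11 rose and 4 fell, 0.351), lipid synthesis (1 of 11 fell, 0.634), ribosomal proteins (0 of 60, 0.32) and foreign tissue markers (1 of 9 fell, 0.304), with the same counts adjusted over the list alone. Without replicate A of XBP-1 RNAi without DTT the calls of TER94 (-1.08), Edem1 (-1.12), CG6766 (-0.98), epsilonCOP (-1.21), Act57B (-1.13) and Ufd1 ended, as they did without at least 1 other array.

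On the arrays labelled IRE1 RNAi, the glutathione transferase genes GstE8 and GstE9 rose with DTT and the cell cycle genes stg and PCNA fell, while SPARC was not past the threshold (-1.03 ± 0.40, adjusted p = 0.0857; 0.00878 with the block). CG3348 rose by 5.50 ± 0.43, Dgp-1 by 4.42 ± 0.41, the insulin-binding ImpL2 by 4.07 ± 0.43, GstE9 by 3.93 ± 0.44 and GstE8 by 3.83 ± 0.36. Hsp83 changed by -3.66 ± 0.35, btn by -3.47 ± 0.58, stg by -3.40 ± 0.37, Idgf3 by -3.0 ± 0.39 and the replication clamp PCNA by -2.88 ± 0.49. Hsc70-3 rose by 1.41 ± 0.42 (adjusted p = 0.0234), a call that quantile normalization ended (adjusted p = 0.0991).

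In limma 203 of 5833 probes rose and 610 fell with DTT on the arrays labelled IRE1 RNAi, with a median change of all probes of -0.24. Higher calls were 25% as deposited, 43.4% with quantile normalization and 50% with centring, so falls outnumbered rises in the first 2 of these. The block gave 1307 probes; without replicate A of the arrays without DTT 512 passed and without replicate C of those with DTT 476. Hsc70-3 was no longer past the threshold without replicate B of the arrays without DTT (1.15), or without replicate A (1.36) or C (1.24) of those with DTT.

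Of 26 cell cycle genes 20 fell on the arrays labelled IRE1 RNAi, and 20 adjusted over the list alone (median -1.76, adjusted p = 7.29e-17; adjusted p = 0.213 with an estimated correlation), Mcm7 at -3.25 and aurB at -2.78. Of 37 proteasome genes 17 fell, and 27 adjusted over the list alone (median -0.94, adjusted p = 9.99e-10; adjusted p = 0.383 with an estimated correlation). Of 20 translocation genes 9 fell, and 11 adjusted over the list alone (median -0.88, adjusted p = 3.55e-05; adjusted p = 0.494 with an estimated correlation), TRAM at -2.08 and Tapdelta at -2.05. Of 17 N-glycosylation genes 5 fell, and 9 adjusted over the list alone (median -0.68, adjusted p = 0.00102; adjusted p = 0.555 with an estimated correlation), Alg10 at -1.67 and OstDelta at -1.49. Of 24 glutathione genes 9 rose and 3 fell, and 12 and 4 adjusted over the list alone (median 1.03, adjusted p = 2.05e-08; adjusted p = 0.349 with an estimated correlation). Of 21 PERK-ATF4 and synthetase genes 5 rose and 1 fell, and 6 and 1 adjusted over the list alone (median 0.88, adjusted p = 3.97e-07; adjusted p = 0.351 with an estimated correlation), Thor at 3.53 and Shmt at -2.17. Of 35 secreted genes 10 fell, and 12 fell and 1 rose adjusted over the list alone, with an adjusted p of 0.0774 that the block took to 0.0489 and quantile normalization to 0.0369. ER chaperones did not pass as a list (3 of 13 rose and 3 fell, and as many adjusted over the list alone, adjusted p = 0.798), nor did ER-associated degradation (2 of 11 fell, and 4 adjusted over the list alone, 0.483), ER-Golgi transport (2 of 24 fell, and 1 adjusted over the list alone, 0.7) and ribosomal proteins (1 of 60 fell, and 0 adjusted over the list alone, 0.74). Heat shock (1 of 11 rose and 4 fell, 0.134), lipid synthesis (1 of 12 rose and 1 fell, 0.986) and foreign tissue markers (1 of 12 fell, 0.853) did not pass either, with the same counts adjusted over the list alone. Without replicate A of the arrays without DTT the calls of Alg10 (-1.29), ERp60, TER94 (-1.05), Ufd1 (-0.95), Spase22-23 (-1.40), Stt3A (-0.77), CHOp24 (-0.84), epsilonCOP (-1.04) and RpLP0 (-1.24) ended. Centring also ended those of Ufd1, Stt3A and CHOp24, and quantile normalization those of Ufd1 and RpLP0.

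Effects of DTT in the 3 arms, which share no array, correlated across 5312 probes with r of 0.736 (control and XBP-1 RNAi), 0.748 (control and arrays labelled IRE1 RNAi) and 0.877 (both RNAi arms), with rho of 0.629, 0.664 and 0.85. Genes are not independent replicates. Among probes tested in both arms, 190 rose in control and XBP-1 RNAi against 19.2 for independent calls, 169 in control and the arrays labelled IRE1 RNAi against 15.3, and 164 in both RNAi arms against 9.12. The same counts for falls were 212 against 30.1, 173 against 27.0 and 444 against 72.3. With centring and block, chosen after seeing the data, the counts for rises were 614 against 280, 563 against 182 and 856 against 294. For falls they were then 729 against 205, 610 against 165 and 757 against 184.

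Under XBP-1 RNAi 8 of 13 ER chaperones and folding enzymes had a lower effect of DTT than in control cells. The oxidase Ero1L rose by 3.50 in control and changed by 0.61 under XBP-1 RNAi, a difference of -2.90 ± 0.54 (adjusted p = 0.0106). The isomerase Pdi differed by -2.75 ± 0.54 (adjusted p = 0.0126; -0.20 in control, -2.96 under XBP-1 RNAi). The calcium-binding scf differed by -3.09 ± 0.58 (adjusted p = 0.0106; 0.62 and -2.47), the translocation component Trp1 by -2.81 ± 0.54 (adjusted p = 0.0106; 2.14 and -0.67) and CG2004 by -3.04 ± 0.51 (adjusted p = 0.00878; 2.67 and -0.37). The chaperones Gp93 (-2.72 ± 0.51) and ERp60 (-2.50 ± 0.52) were also past the threshold. Without replicate A of control with DTT none of these passed, with scf at -2.80, CG2004 at -2.77, Ero1L at -2.73, Trp1 at -2.69, Gp93 at -2.46, Pdi at -2.38 and ERp60 at -2.31. Trp1 was also not past it without C of control with DTT (-2.59), and Pdi without A of XBP-1 RNAi without DTT (-2.52). ERp60 was not without B (-2.37) or C (-2.38) of control without DTT, C of control with DTT (-2.55) or A of XBP-1 RNAi without DTT (-2.15). Hsc70-3 was not (-1.68 ± 0.60, adjusted p = 0.284), nor was SPARC (-0.03 ± 0.56, adjusted p = 0.993).

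In limma 44 of 5483 probes differed between XBP-1 RNAi and control in their response to DTT, all lower under XBP-1 RNAi as deposited. With centring 17 were higher and 60 lower (22.1% higher), with quantile normalization 12 and 95 (11.2%), and with centring and block, chosen after seeing the data, 187 and 214 (46.6%). Lower calls thus outnumbered higher ones in each of these. At an unadjusted p under 0.05, 50 were higher and 389 lower as deposited, 262 and 412 with quantile normalization, and 467 and 345 with centring. The median difference of all probes was -0.28. Single arrays moved this count by more than 1.5 times. Without replicate A, B or C of control without DTT it was 84, 8 and 12. Without A, B or C of control with DTT it was 0, 94 and 7. Without A or C of XBP-1 RNAi without DTT it was 6 and 10, and without A or C of XBP-1 RNAi with DTT 26 and 15.

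The 13 ER chaperones had a median difference of -2.17, or -1.89 relative to all probes; 8 were lower, and 13 adjusted over the list alone (adjusted p = 5.19e-30; adjusted p = 0.00103 with an estimated correlation). Of 20 translocation genes 2 were lower, and 16 adjusted over the list alone (median -1.40, adjusted p = 4.43e-16; adjusted p = 0.144 with an estimated correlation). Of 24 ER-Golgi genes 3 were lower, and 18 adjusted over the list alone (median -1.24, adjusted p = 3.33e-16; adjusted p = 0.115 with an estimated correlation). Of 11 degradation genes 2 were lower, and 4 adjusted over the list alone (median -0.96, adjusted p = 7.47e-08; adjusted p = 0.144 with an estimated correlation). Of 17 N-glycosylation genes 0 were lower, and 7 adjusted over the list alone (median -0.65, adjusted p = 1.28e-06; adjusted p = 0.349 with an estimated correlation). No member passed in 3 further lists, with 0 adjusted over the list alone: secreted genes (median 0.36, adjusted p = 0.000771; adjusted p = 0.565 with an estimated correlation), proteasome (median -0.38, adjusted p = 0.00324; adjusted p = 0.804 with an estimated correlation) and foreign tissue markers (median 0.64, adjusted p = 0.0267; adjusted p = 0.482 with an estimated correlation). Quantile normalization took the proteasome list to 0.217 and the markers to 0.0899. The lists that did not pass were PERK-ATF4 (0.736), heat shock (0.284), glutathione (0.415, and 0.0288 with quantile normalization), lipid synthesis (0.415), cell cycle (0.794) and ribosomal proteins (0.284), with 0 members past the threshold and 0 adjusted over the list alone.

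Probes that rose with DTT in control and had a lower effect under XBP-1 RNAi numbered 33, of 32 genes, and 29 of them had a negative effect there. Probes that rose in control and had a higher effect under XBP-1 RNAi numbered 0 as deposited. The counts were 44 against 3 with centring and 133 against 17 with centring and block. Both conditions use the same control arrays. Noise that raises the effect in control cells therefore favours the class and works against the mirrored count, so the contrast of these counts is no test. As deposited, the 32 genes of the class included 5 ER chaperones, 2 degradation genes, 1 translocation gene and 3 ER-Golgi genes. The largest difference was that of CG10184, at -4.03 ± 0.73 (4.21 in control, 0.18 under XBP-1 RNAi), with sel (-2.67 ± 0.60), meigo (-2.63 ± 0.59), Grasp65 (-2.47 ± 0.50), Cog6 (-2.38 ± 0.53) and Acat2 (-2.37 ± 0.47) also among the 10 largest. CG10184 was no longer past the threshold without A of control with DTT (-3.88), and had too few values without any of 6 other arrays. The differences of sel, meigo, Grasp65, Cog6 and Acat2 were not past it when any 1 of 5 arrays was left out. These arrays were B of control without DTT, A and C of control with DTT, and A and C of XBP-1 RNAi without DTT. In this order the differences stood at -2.45, -2.37, -2.44, -2.49 and -2.54 for sel, and at -2.35, -2.47, -2.43, -2.39 and -2.59 for meigo. Grasp65 stood at -2.30, -2.26, -2.38, -2.31 and -2.37, Cog6 at -2.18, -2.24, -2.34, -2.14 and -2.38, and Acat2 at -2.26, -2.24, -2.28, -2.32 and -2.27. Without C of control without DTT sel (-2.67), meigo (-2.67) and Cog6 (-2.45) did not pass either. Without B of XBP-1 RNAi with DTT sel (-2.41) and meigo (-2.49) did not, nor did meigo without C (-2.59), and Cog6 had too few values without either. Without replicate A, B or C of control without DTT the class held 58, 4 and 8 probes. Without A, B or C of control with DTT it held 0, 58 and 4. Without A or C of XBP-1 RNAi without DTT it held 4 and 4, and without A, B or C of XBP-1 RNAi with DTT 16, 21 and 10.

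**Figure D3:**
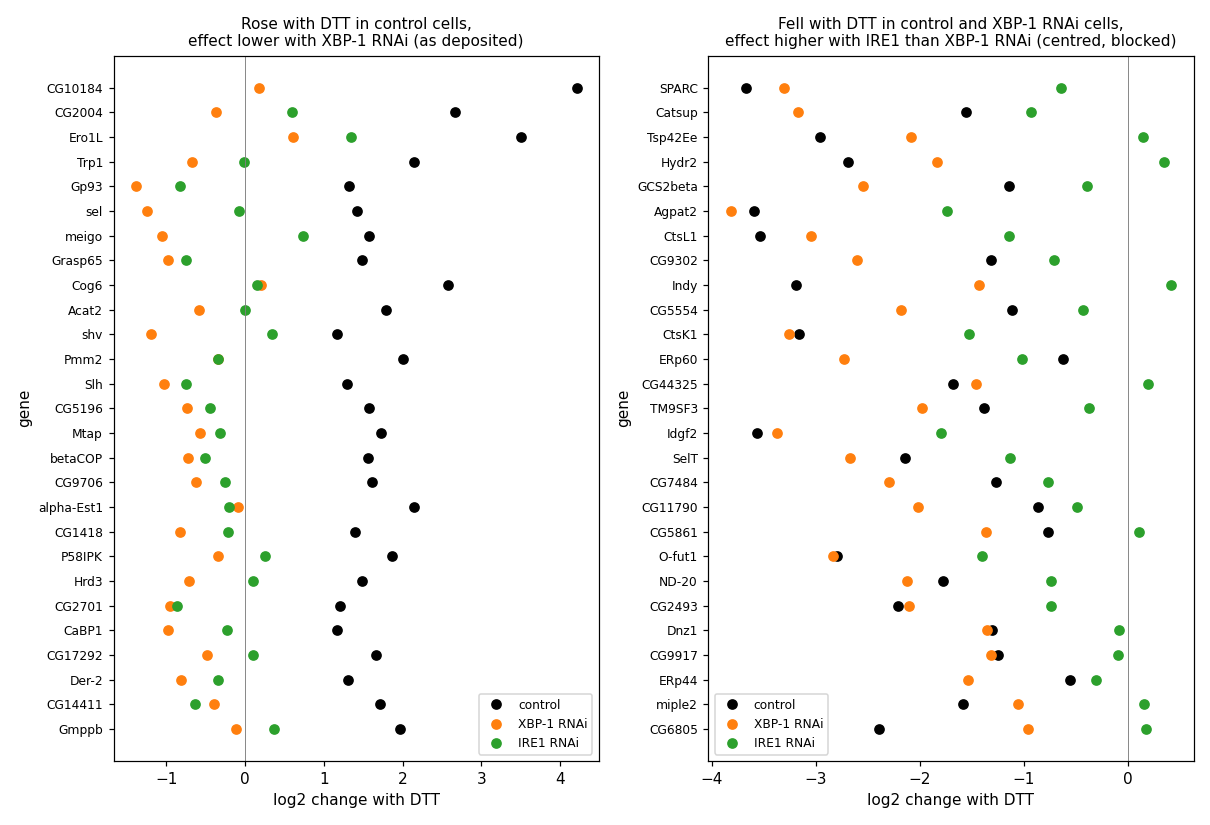
Log2 change with DTT (horizontal axis) of genes (vertical axis) that rose in control cells and had a lower effect under XBP-1 RNAi, as deposited (left, the 27 with the largest difference), and of 27 probes that fell in control and XBP-1 RNAi cells and had a higher effect on the arrays labelled IRE1 RNAi than under XBP-1 RNAi, with centring and block (right). Dots are the effects in control, XBP-1 RNAi and the arrays labelled IRE1 RNAi; in the left panel Ero1L stood at 3.50 in control and 0.61 under XBP-1 RNAi.

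On the arrays labelled IRE1 RNAi, the metabolite transporter Indy and the hydrolase Hydr2, which fell with DTT in control cells, had effects near 0. Indy differed by 3.09 ± 0.57 (adjusted p = 0.037; -3.05 in control, 0.03 on these arrays) and Hydr2 by 2.52 ± 0.51 (adjusted p = 0.037). The Golgi tethering gene Cog6 differed by -2.43 ± 0.50 (adjusted p = 0.0407; 2.58 and 0.15) and CG14411 by -2.34 ± 0.46 (adjusted p = 0.037; 1.71 and -0.63). The other call, Ugt302C1 (0.80 and 3.64, adjusted p = 0.037), lay outside the naming rule and was chosen after its values were seen. None of the 5 calls remained without C of control without DTT, C of control with DTT, A of the arrays labelled IRE1 RNAi without DTT or B of those with DTT. In this order Indy then stood at 3.11, 3.00, 2.98 and 2.78, Hydr2 at 2.52, 2.59, 2.65 and 2.46, Cog6 at -2.50, -2.40, -2.18 and -2.38, and CG14411 at -2.21, -2.39, -2.16 and -2.37. Ugt302C1 had too few values without the first and stood at 2.74, 2.91 and 2.64 without the others. Without B of control with DTT Indy (2.86), Hydr2 (2.28) and Ugt302C1 (2.63) did not pass. Without A of it Cog6 (-2.30) and CG14411 (-2.24) did not, nor did Cog6 without B of control without DTT (-2.24). Without A of the arrays labelled IRE1 RNAi with DTT Hydr2 (2.32), Cog6 (-2.33), CG14411 (-2.17) and Ugt302C1 (2.78) did not, and without B of those without DTT Hydr2 (2.42) and Cog6 (-2.44). Cog6 also missed the threshold without C of XBP-1 RNAi without DTT or B of XBP-1 RNAi with DTT (-2.43 in both), and Ugt302C1 had too few values without A of control without DTT. SPARC differed by 2.50 ± 0.56 (adjusted p = 0.0694) and Hsc70-3 by -1.52 ± 0.60 (adjusted p = 0.43), neither past the threshold as deposited. SPARC passed with centring (3.03, adjusted p = 0.00161), with centring and block (adjusted p = 0.000306), with the block (adjusted p = 4.45e-05) and with quantile normalization, and Hsc70-3 with the block alone (adjusted p = 0.0377).

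In limma these 5 of 5594 probes were the calls, 3 higher and 2 lower, or 60% higher as deposited and 71.4% after centring; the median difference of all probes was -0.44. The block gave 153, 30 higher and 123 lower (19.6% higher), and array weights 41 higher and 1300 lower, so the direction of the calls turns with the setting. The count was 27 without replicate A and 0 without C of control without DTT, and 0 without C of control with DTT. It was 0, 3 and 8 without A, B or C of the arrays labelled IRE1 RNAi without DTT, and 1, 0 and 19 without A, B or C of those with DTT.

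No member of the ER lists passed over all probes tested in this difference. ER chaperones had 9 of 13 lower adjusted over the list alone (median -0.99, adjusted p = 4.4e-09; adjusted p = 0.225 with an estimated correlation), and ER-Golgi transport 12 of 24 adjusted over the list alone (median -0.91, adjusted p = 6.33e-09; adjusted p = 0.309 with an estimated correlation). Translocation had 11 of 20 adjusted over the list alone (median -0.86, adjusted p = 2.67e-08; adjusted p = 0.349 with an estimated correlation) and degradation 5 of 11 adjusted over the list alone (median -0.79, adjusted p = 9.67e-05; adjusted p = 0.349 with an estimated correlation). The secreted list had a median of 0.90 (adjusted p = 6.73e-12; adjusted p = 0.213 with an estimated correlation) and 1 of 35 past the threshold adjusted over the list alone. Ribosomal proteins had a median of -0.43 (adjusted p = 0.000476; adjusted p = 0.876 with an estimated correlation) and the proteasome -0.54 (adjusted p = 3.32e-06; adjusted p = 0.555 with an estimated correlation), each with 0 members adjusted over the list alone. The other 7 lists did not pass and had 0 members adjusted over the list alone, N-glycosylation and heat shock at 0.0796 each (heat shock 0.0415 with the block) and glutathione at 0.2 (0.0183 with quantile normalization) among them.

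Between the RNAi arms, the response of SPARC to DTT was 2.54 ± 0.56 higher on the arrays labelled IRE1 RNAi than under XBP-1 RNAi, with an adjusted p of 0.209 as deposited. The SPARC difference passed with centring (2.67, adjusted p = 0.0151), with centring and block (adjusted p = 0.00203), with the block (adjusted p = 6.18e-05) and with quantile normalization. That of Hsc70-3 differed by 0.16 ± 0.60 (adjusted p = 0.999). In limma 0 of 5417 probes passed, 61 were higher and 12 lower at an unadjusted p under 0.05, and the median difference of all probes was -0.18. The block gave 13 probes and centring 8. Without replicate C of the arrays labelled IRE1 RNAi with DTT 1 probe passed.

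The 13 ER chaperones had a median difference of 0.74 between the RNAi arms, or 0.93 relative to all probes, with 2 higher adjusted over the list alone (adjusted p = 1.27e-17; adjusted p = 0.0433 with an estimated correlation). Lists with smaller shifts were N-glycosylation (0.44, adjusted p = 2.26e-06; adjusted p = 0.349 with an estimated correlation), ER-Golgi transport (0.41, adjusted p = 4.59e-05; adjusted p = 0.482 with an estimated correlation), translocation (0.38, adjusted p = 3.88e-05; adjusted p = 0.494 with an estimated correlation) and ER-associated degradation (0.29, adjusted p = 0.016; adjusted p = 0.555 with an estimated correlation, and 0.0721 with quantile normalization). Secreted genes stood at 0.38 with 1 of 34 higher adjusted over the list alone (adjusted p = 7.3e-07; adjusted p = 0.349 with an estimated correlation), and ribosomal proteins at -0.19 (adjusted p = 0.00396; adjusted p = 0.921 with an estimated correlation, and 0.0654 with quantile normalization). Apart from the chaperones and secreted genes, each list had 0 members adjusted over the list alone. The other 7 lists did not pass. Quantile normalization took the cell cycle list from 0.0812 to 0.00577, and centring the foreign tissue markers from 0.0721 to 0.0399.

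The class of genes that fell in control cells had a negative mean change in both RNAi arms. The 310 probes chosen on the control arrays, 187 of them complete on the RNAi arrays, changed by -1.46 on the arrays labelled IRE1 RNAi and by -1.75 under XBP-1 RNAi, a difference of 0.29. In an exact permutation test 186 of 400 arrangements matched it (p = 0.465), while 63.6% of the probes were higher on the arrays labelled IRE1 RNAi. With the class chosen by a 1.5-fold change and no test, 460 complete probes gave a difference of 0.077 (exact permutation p = 0.825), with 45% of the probes higher and a median difference of -0.06. By replicate letter the difference was 0.084 (A), 0.029 (B) and 0.747 (C). With the letters paired the exact permutation p was 0.25, the smallest that 8 arrangements can give, and 0.5 after centring, where letter A stood at -0.02. The 441 probes that rose in control, 294 complete, changed by 1.05 and 1.15, a difference of -0.10 (exact permutation p = 0.765; -0.15 and 0.63 with the class chosen by 1.5-fold). Single arrays moved the difference of the repressed class by more than 1.5 times. It was 0.44 without replicate A and 0.03 without C of XBP-1 RNAi with DTT, and 0.16 without A and 0.44 without B of XBP-1 RNAi without DTT. On the arrays labelled IRE1 RNAi it was 0.17 without B and 0.47 without C of those with DTT, and 0.17 without C of those without DTT. Probes that fell in control and XBP-1 RNAi cells and had a higher effect on the arrays labelled IRE1 RNAi than under XBP-1 RNAi numbered 0 in limma, 5 with centring, 7 with the block and 27 with centring and block. These conditions share the XBP-1 RNAi arrays, so noise on those arrays can raise the count.

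Without DTT, RNAi gave 0 calls in limma for either target. At an unadjusted p under 0.05, 60 of 5729 probes were higher and 17 lower under XBP-1 RNAi, and 18 of 5914 higher and 6 lower on the arrays labelled IRE1 RNAi. Under XBP-1 RNAi these became 51 higher and 262 lower with centring and 82 and 92 with quantile normalization. For the arrays labelled IRE1 RNAi they became 63 higher and 81 lower with centring, but 91 and 48 with quantile normalization and 236 and 218 with centring and block. The median differences of all probes were 0.22 and 0.03, and the block gave 2 and 1 probes. Both comparisons subtract the same 3 control arrays, so a like shift in both is no independent evidence. The ribosomal protein list stood at 0.36 relative to all probes under XBP-1 RNAi (adjusted p = 2.75e-11; adjusted p = 0.555 with an estimated correlation) and at 0.51 on the arrays labelled IRE1 RNAi (adjusted p = 5.84e-24; adjusted p = 0.349 with an estimated correlation). Glutathione genes stood at 0.32 (adjusted p = 0.000702; adjusted p = 0.565 with an estimated correlation) and 0.40 (adjusted p = 2.93e-06; adjusted p = 0.404 with an estimated correlation). Proteasome genes stood at 0.24 (adjusted p = 0.00023; adjusted p = 0.692 with an estimated correlation) and 0.25 (adjusted p = 0.000151; adjusted p = 0.692 with an estimated correlation), lost with quantile normalization at 0.3 and 0.942. In XBP-1 RNAi secreted genes stood at -0.18 (adjusted p = 0.011; adjusted p = 0.76 with an estimated correlation) and foreign tissue markers at -0.23 (adjusted p = 0.0227; adjusted p = 0.482 with an estimated correlation, and 0.165 with quantile normalization). On the arrays labelled IRE1 RNAi translocation genes stood at 0.33 (adjusted p = 0.00926; adjusted p = 0.761 with an estimated correlation, and 0.63 with quantile normalization). No member of any list passed, over all probes tested or adjusted over the list alone. The remaining lists did not pass, and ER chaperones on the arrays labelled IRE1 RNAi went from 0.0651 to 0.0173 with the block and 0.0277 with quantile normalization.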

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

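Chosen after the result was seen were the tests for the IRE1 probe, the test of array scaling for the ER chaperones, the fits with centring and replicate block together, and, for the repressed class, the use of the same probes and the removal of each other array; the other tests were chosen before.

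The response to DTT differed between XBP-1 RNAi and control cells by a test of the difference itself for 44 probes, all lower under XBP-1 RNAi as deposited. With centring 17 were higher and 60 lower, with quantile normalization 12 and 95, and with centring and block 187 and 214. Among those named above were scf (-3.09), CG2004 (-3.04), Ero1L (-2.90), Trp1 (-2.81) and Pdi (-2.75). The ER chaperone list had a median difference of -2.17. On the arrays labelled IRE1 RNAi the response differed from control for 5 probes, among them Indy (3.09), Hydr2 (2.52), Cog6 (-2.43) and CG14411 (-2.34). Between the RNAi arms the ER chaperone list differed by a median of 0.74.

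The IRE1 probe was higher on the arrays labelled IRE1 RNAi than on most others. A swap of the whole group with the control or the XBP-1 RNAi arrays is argued against, since these 2 groups differed by 0.03 relative to array medians, against a mean of 1.91 on the arrays labelled IRE1 RNAi and -0.33 on the other 12, if XBP-1 RNAi itself leaves IRE1 mRNA unchanged. Replicate C without DTT, at 0.35, lay below 1 of the other 12, replicate C of XBP-1 RNAi with DTT (0.48), within the spread between arrays (SD 0.42). A swap of these 2 is argued against by their centred class means, each on the side of its own DTT label. The repressed class stood at 0.624 and -0.603 on them, and the induced class at -0.417 and 0.685. A swap with a control or XBP-1 RNAi array without DTT stays open for this replicate, though none of those stood above -0.28. Labelled double-stranded RNA binding to the probe might raise it, but the XBP-1 probes were lower on the arrays labelled XBP-1 RNAi by -0.55, and since the positions of probes and double-stranded RNA are not known, this stays open too. A true rise of IRE1 mRNA was not tested.

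The ER chaperone list had a lower effect of DTT under XBP-1 RNAi than in control cells. Array scaling as the whole cause is argued against by the median after centring, -1.77. Removed spots are argued against, since the 13 members tested have 0 empty cells on the 18 arrays (median -2.17). A dependence of these mRNAs on XBP-1 may be the source and remains a hypothesis. Chance was argued against only for the count of calls with centring and block, and the labels do not show separate cultures. The lower values of the XBP-1 probes did not pass limma's test adjusted over all probes (adjusted p = 0.959). Control cells received no double-stranded RNA, so an effect of double-stranded RNA as such cannot be told apart in this comparison. The list also had a lower median than control on the arrays labelled IRE1 RNAi, whose cells received double-stranded RNA too. Both differences subtract the same control arrays, so the second is no independent evidence. Between the RNAi arms the list was higher on the arrays labelled IRE1 RNAi by a median of 0.74. An effect of double-stranded RNA alike in both arms would not give that difference. How much of the -2.17 it could give was not tested.

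The repressed class fell less on the arrays labelled IRE1 RNAi than under XBP-1 RNAi by 0.29, a difference that did not pass its exact permutation test and was 0.077 with the class chosen by 1.5-fold (p = 0.825, 45% of probes higher). A smaller response throughout on these arrays was tested with the induced class, whose ratio of centred effects, IRE1 RNAi over XBP-1 RNAi, was 1.01. As deposited these effects were 1.05 and 1.15. XBP-1 RNAi may itself lower that class, so the ratio argues only against a response of the induced probes smaller than under XBP-1 RNAi. The array with most removed spots stays open: on the same 548 probes, 0.43 of the centred difference was left without replicate A of the arrays labelled IRE1 RNAi with DTT, but 0.48 without replicate C of XBP-1 RNAi with DTT. Array scaling stays open too, with a centred difference of 0.181. A dependence of these falls on IRE1 was not shown.

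Other splits of the samples were counted for each fit. The 10 splits of 6 arrays are too few to judge chance: for DTT in control the real count was 694 and the highest other 0 (1 of 10 as large), under XBP-1 RNAi 921 and 1 (1 of 10), on the arrays labelled IRE1 RNAi 813 and 7 (1 of 10), and without DTT 0 and 0 for XBP-1 RNAi (10 of 10) and 0 and 22 for the arrays labelled IRE1 RNAi (10 of 10). For the differences of responses 100 of 200 arrangements were fitted, and chance was not excluded for XBP-1 RNAi minus control (44 against a highest other of 2224, 5 as large), IRE1 RNAi minus control (5 against 319, 16 as large) or the XBP-1-dependent induction (33 against 698, 5 as large). For IRE1 RNAi minus XBP-1 RNAi (0 against 442) and the repression class (0 against 2) the real count was 0, so all 100 were as large and nothing was decided. Why some arrangements call many times the real count was not tested. The shared replicate letters and the unscaled arrays may both contribute and were not told apart. With centring and block, 1 of all 32 swaps within letters was as large for XBP-1 RNAi minus control (401 against 266). This is the smallest share that 32 swaps can give, in a fit chosen after the data were seen, and the other differences tested so did not reach it. It argues against chance for the count of that fit without excluding it, and not for the 44 as deposited. The 6 pairs of arrays swapped deviated together, with correlations from 0.259 to 0.618, and the 1 pair that did not (0.012) is not among them. By the same swaps chance was not excluded for IRE1 RNAi minus control (283 against 437, 4 as large) or IRE1 RNAi minus XBP-1 RNAi (49 against 115, 7 as large).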

How the results depend on the processing

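Chosen after seeing the data were centring together with the replicate block, the correlation estimated in that fit, and the naming of probes by the platform annotation; the other alternatives were chosen before. For the changes given here the cause was not tested, except that fewer arrays or probes were fitted where arrays were left out or only complete probes used.

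With median centring, 1437 probes passed for DTT in control, 1902 under XBP-1 RNAi, 1299 on the arrays labelled IRE1 RNAi, 77 for XBP-1 RNAi minus control, 63 for IRE1 RNAi minus control, 8 for IRE1 RNAi minus XBP-1 RNAi and 5 for the repression class. With quantile normalization the same counts were 1696, 1566, 1278, 107, 85, 11 and 8, and the XBP-1-dependent induction held 76. The mirrored count of the induction, against which the shared control arrays work, was 0 there, 3 with centring (against 44), 2 with the block, 1 with array weights and 17 with centring and block. With the block they were 1164, 1504, 1307, 196, 153, 13 and 7, the induction held 98, and RNAi without DTT gave 2 (XBP-1) and 1 (IRE1). In the block fit limma estimated an infinite prior degree of freedom in all 8 contrasts, so its p-values are probably too small and these larger counts, and the calls it kept, are no evidence of stability. With centring and block, where the prior was 7.49 to 8.11, they were 2058, 2757, 1979, 401, 283, 49 and 27, and the induction held 133.

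Array weights gave 2991, 1457 and 1584 probes for DTT in control, XBP-1 RNAi and the arrays labelled IRE1 RNAi, 738 for XBP-1 RNAi minus control, 1341 for IRE1 RNAi minus control, 6 for IRE1 RNAi minus XBP-1 RNAi, 575 for XBP-1 RNAi without DTT, 4 for the repression class and 491 for the induction. Of the 575, 574 were higher, while with centring 262 of the probes at an unadjusted p under 0.05 were lower and 51 higher. Fitting the weights gave convergence warnings, so these counts are the least certain. Complete probes alone gave 17 for IRE1 RNAi minus control. The arrays of the contrast alone gave 81 for XBP-1 RNAi minus control, 0 for IRE1 RNAi minus control and 2 for XBP-1 RNAi without DTT, with an infinite prior in 3 of 8 fits.

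Leaving out each array in turn, counts ran from 526 to 988 for DTT under XBP-1 RNAi (526 without replicate C of XBP-1 RNAi with DTT), from 476 to 874 on the arrays labelled IRE1 RNAi (476 without replicate C with DTT), from 0 to 94 for XBP-1 RNAi minus control (0 without replicate A and 94 without replicate B of control with DTT), from 0 to 27 for IRE1 RNAi minus control, from 0 to 1 for IRE1 RNAi minus XBP-1 RNAi and for IRE1 RNAi without DTT, and from 0 to 58 for the induction. The repressed class difference ran from 0.029 to 0.474, the induced class difference from -0.247 to 0.068, the SPARC difference between XBP-1 RNAi and control from -0.38 to 0.37, the Hsc70-3 difference between the RNAi arms from -0.20 to 0.78 and the DTT effect in control cells of the first XBP-1 probe from -0.048 to 0.51.

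With the class chosen by 1.5-fold and no test the repressed class difference was 0.077 (exact permutation p = 0.825) and the induced -0.154 (exact permutation p = 0.63). Some results that were not past the threshold changed direction. The induced class difference became 0.008 with centring and also with centring and paired differences. The SPARC difference between XBP-1 RNAi and control became 0.36 with centring, 0.40 with quantile normalization and 0.36 with centring and block.

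Lists that changed direction had these adjusted p-values. With centring they were translocation in control (0.976), lipid synthesis in control (0.817), on the arrays labelled IRE1 RNAi (0.645) and in IRE1 RNAi minus control (0.823), and glutathione in IRE1 RNAi minus XBP-1 RNAi (0.966). With quantile normalization they were translocation (0.852) and lipid synthesis (0.966) in control; lipid synthesis (0.823), ribosomal proteins (0.837) and foreign tissue markers (0.852) on the arrays labelled IRE1 RNAi with DTT; and PERK-ATF4 (0.78) and lipid synthesis (0.837) in IRE1 RNAi minus control. In XBP-1 RNAi without DTT they were N-glycosylation (0.728), lipid synthesis (0.789) and cell cycle (0.442). On the arrays labelled IRE1 RNAi without DTT they were N-glycosylation (0.262), ER-Golgi transport (0.923), heat shock (0.76), cell cycle (0.94) and the proteasome (0.942, past the threshold as deposited). With the block they were translocation (0.971) and heat shock (0.873) in control, PERK-ATF4 (0.952) and lipid synthesis (0.775) in IRE1 RNAi minus control, and ER-Golgi transport (0.957) on the arrays labelled IRE1 RNAi without DTT. With the mean of the probes of a gene it was lipid synthesis on the arrays labelled IRE1 RNAi (0.989). With the correlation estimated after centring and block they were translocation (0.964) and lipid synthesis (0.957) in control, lipid synthesis on the arrays labelled IRE1 RNAi (0.742) and in IRE1 RNAi minus control (0.742), and glutathione in IRE1 RNAi minus XBP-1 RNAi (0.957).

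Of the 54 list tests past the threshold, 53 remained so with centring, 45 with quantile normalization, 54 with the block and 54 with the mean of probes. With quantile normalization ribosomal proteins passed in 3 of 8 contrasts, the proteasome in 4 and foreign tissue markers in 0, and with the block heat shock passed in 1. With the estimated correlation ER chaperones passed in 2 contrasts and each of 11 other lists in 0. With the correlation estimated after centring and block 27 of the 54 remained, with ER chaperones, translocation and glutathione passing in 2 contrasts each, ER-Golgi transport in 3, ribosomal proteins in 1 and the proteasome in 0. With the platform's naming 0 of 103 list tests passed, so each of 11 lists that had passed went to 0.

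Of 172 called values of named genes, 4 were lost with centring, 5 with quantile normalization and 0 with the block or with centring and block. Over the arrays left out, 177 of 3078 values were lost. Hsc70-3 in the XBP-1 RNAi and IRE1 RNAi arms was lost with quantile normalization. Values that passed only in alternatives included the SPARC differences of IRE1 RNAi minus control and minus XBP-1 RNAi, which passed with centring, quantile normalization, the block, and centring and block. With the block alone they also included SPARC on the arrays labelled IRE1 RNAi with DTT (adjusted p = 0.00878), Hsc70-3 in XBP-1 RNAi minus control (adjusted p = 0.0108) and in IRE1 RNAi minus control (adjusted p = 0.0377), and the IRE1 probe without DTT (adjusted p = 4.23e-07). Signal over background per spot was not analysed here.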
